A study of Homo sapiens with 8 samples.

How the data were processed

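Total RNA of KYSE150 cells, an esophageal squamous cell carcinoma line, was extracted with TRIzol per the labels. Libraries made with the VAHTS Universal V6 kit were sequenced as 150 bp paired-end reads on an Illumina NovaSeq instrument, and the reads were filtered with fastp. The genome build is hg38 per the labels. The aligner, the counting tool and the annotation release are not given in the sources used here. The deposited count table holds raw counts per gene for 15852 genes in 8 libraries, 4 controls and 4 with BOLA3-L knockdown, with gene symbols, Entrez identifiers and gene ontology and KEGG terms. A second deposited table holds FPKM values that the authors computed by scaling each count to the length of the gene in kilobases and to the total of the library. All 110558 of the 110558 FPKM values above 0 equal the count scaled by the library total and 1 length per gene to within 1e-06, so the FPKM table is not independent of the counts. The counts are per gene, so isoforms of BOLA3 are not separated. Depth ranged from 31178036 to 35147860 counts per library, at which 3 counts correspond to 0.0854 to 0.0962 CPM. Whether the errors given here cover differences between separate cultures is not known, since the sources used here do not say how the libraries of a group were made.

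Counts were normalized by TMM and filtered with filterByExpr, which left 11841 genes. The groups were compared with edgeR's robust quasi-likelihood F-test and p-values were adjusted by Benjamini-Hochberg at 0.05. A change of at least 2-fold means an absolute log2 change of at least 1. Group levels are mean CPM ± SD, and the SE of a log2 change is its absolute value over the square root of the F statistic. BOLA3 was also compared with an exact two-sided permutation test over the 70 assignments of the libraries. Gene lists were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 34 lists with tested members. Terms with 10 to 500 tested members were tested with Fisher's exact test, one-sided for over-representation, among genes that rose and, apart from them, genes that fell, with all tested genes as background and adjustment per direction and vocabulary. Principal components were computed on log2 CPM. Calculations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

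The tests, the gene lists, the alternatives and the rule for named genes were set before the data were examined, except where another order is stated. The rule names BOLA3, HNRNPC and E2F7. Among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, it adds the 8 largest rises, the 8 largest falls and the 4 smallest p-values in each direction. It also takes up to 4 members of each list by smallest p. Some of the genes it takes are not described here. The lists cover iron-sulfur cluster assembly, lipoic acid, the respiratory chain, other metabolism, stress, proliferation, adhesion, inflammation, signalling, RNA processing and ribosomes, and markers of fibroblasts, leukocytes and endothelium.

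The alternatives set beforehand were RLE size factors and upper quartile normalization in the edgeR fit, no filter on low counts, a minimum of 1 CPM in 4 libraries, the replicate number as a block, each library left out in turn, DESeq2, and limma on log2 FPKM with a minimum of 0.5 FPKM in 4 libraries and a pseudocount of 1 or 0.1, or with a pseudocount of 1 and no minimum. For the lists they were camera with an estimated correlation and fry, and for the terms camera. Alternatives chosen after seeing the data were offsets corrected for transcript GC content, the same without BOLA3-L knockdown replicate 1, and the removal of genes with near-identical copies. A gene counts as having a near-identical copy when at least 50% of its 75-base windows, taken every 25 bases, also occur in transcripts of other genes. Coordinates come from RefSeq on GRCh38.p14 and exons, GC content and shared sequence from GENCODE v29; 11828 tested genes were found in the first and 11789 (99.6%) in the second.

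The steps were tested on simulated data. Of planted changes of 1.25, 1.5, 2 and 3-fold, edgeR recovered 62%, 96%, 98% and 100%, and it called 7 unchanged genes. Those draws held no GC trend. In a separate simulation with a GC trend in BOLA3-L knockdown replicate 1, edgeR recovered 44%, 84%, 94% and 98% and called 1 unchanged gene. GC-corrected offsets there recovered 70%, 90%, 94% and 98% and called 7. The simulated trend rose with GC content in that library alone, while the real deviation of that library ran the other way. A GC trend shared by the libraries of a group was not simulated. Camera found the planted list and 0 others, and Fisher's test found the planted term and 1 other. Simulated genes were drawn independently, so this does not show how often camera calls lists whose genes vary together.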

Results

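RNA was sequenced from KYSE150, an established esophageal squamous cell carcinoma line, in 4 control libraries and 4 libraries with knockdown of the BOLA3-L isoform. The totals over 15852 listed genes were 31215897, 31849697, 33195901 and 33150309 counts in control replicates 1 to 4 and 31178036, 35147860, 34163297 and 33855632 counts in BOLA3-L knockdown replicates 1 to 4. Of the listed genes, 11841 had enough counts to be tested. The first principal component held 46.5% of the variance and put the controls (-15.9 to -14.4) apart from the knockdown libraries (14.6 to 15.6). The next component held 14.4% and put BOLA3-L knockdown replicate 1 (20.1) apart from the other knockdown libraries (-10.1 to -4.81). The sources used here do not say whether the 4 libraries of a group were separate cultures, so the spread between them can be technical.

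The comparison asks which genes respond to loss of the BOLA3 isoform that the labels call BOLA3-L, in a study of BOLA3 exon 3 inclusion and the splicing regulator HNRNPC. BOLA3, a mitochondrial protein of iron-sulfur cluster transfer, fell from 20.8 ± 1.26 CPM (SD, n = 4) in controls to 6.58 ± 0.531 CPM (SD, n = 4), or 31.7% of control. Of 15 tested squamous lineage genes 14 fell (adjusted p = 0.0802 with an estimated correlation), among them the keratins KRT14 (86.3 ± 2.91 to 39.0 ± 4.03 CPM, SD, n = 4 each) and KRT5 (3132 to 1936 CPM). Of 22 cholesterol genes 13 fell and 3 rose (adjusted p = 0.0802 with an estimated correlation), with HMGCS1 and the regulator INSIG1 among the falls. Of 32 glycolysis and hypoxia response genes 17 fell and 3 rose (adjusted p = 0.237 with an estimated correlation), with NDRG1 and PKM among the falls. Of 24 NRF2 antioxidant genes 11 rose and 1 fell (adjusted p = 0.201 with an estimated correlation), and the rises included the thioredoxin reductase TXNRD1 (log2 change 0.44) and the quinone reductase NQO1 (0.35).

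BOLA3 was counted at 21.6, 19.1, 20.5 and 21.8 CPM in control replicates 1 to 4 and at 6.06, 6.64, 6.33 and 7.29 CPM in knockdown replicates 1 to 4. These values rest on 604 to 718 counts per control library and 191 to 248 per knockdown library. The log2 change was -1.66 (SE 0.0821, edgeR adjusted p 6.9e-11), and an exact two-sided permutation test gave p = 0.0286, the smallest that 70 assignments of 4 against 4 allow. BOLA3 (identifier 388962) lies on chromosome 2 from 74135400 to 74147912 in GRCh38. Of its protein-coding transcripts in GENCODE v29, BOLA3-202 (639 bases) holds an exon 3 of 89 bases at 74142272 to 74142360 on the minus strand, which BOLA3-201 (444 bases) lacks. The table counts all transcripts of the gene together, so the isoforms cannot be separated and the fall of the L isoform itself was not measured. HNRNPC stood at 802 ± 27.7 CPM in controls and 782 ± 25.4 CPM after knockdown (SD, n = 4 each), a log2 change of -0.04 that did not pass the test (adjusted p 0.449). E2F7, a repressor of cell cycle genes, stood at 99.6 ± 2.33 and 102.0 ± 7.65 CPM (SD, n = 4 each) and did not pass it either (adjusted p 0.642).

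**Figure D1:**
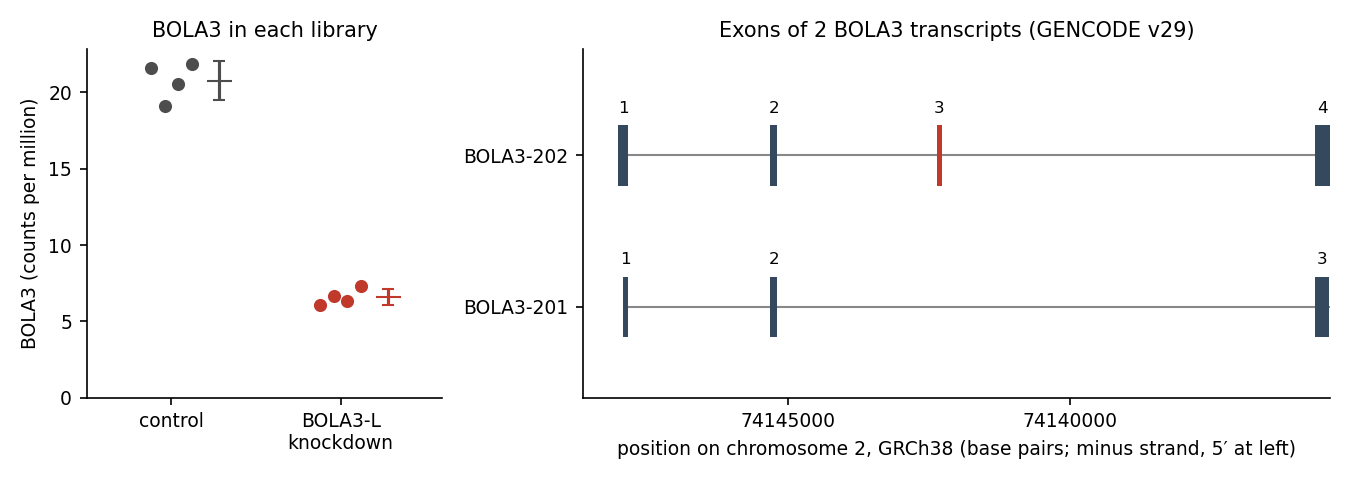
Left: BOLA3 in CPM (y axis) in each of the 4 control and 4 BOLA3-L knockdown libraries, as points with the group mean and SD; the control libraries lie between 19.1 and 21.8 and the knockdown libraries between 6.06 and 7.29. Right: exons of BOLA3-202 (4 exons, exon 3 in red) and BOLA3-201 (3 exons), drawn to scale along chromosome 2 with the 5′ end at the left.

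After knockdown, 1777 of the tested genes rose and 1853 fell, together 30.7% of those tested. Which direction was more frequent depended on the processing and the libraries used. Rises outnumbered falls after upper quartile normalization (1897 against 1724) and with limma on log2 FPKM (1870 against 1385). They also did, narrowly, with no filter on low counts (1787 against 1783) and without control replicate 2 (1422 against 1419). Falls outnumbered rises with RLE size factors (1770 rose, 1858 fell) and in DESeq2 (1830 rose, 1911 fell). Most changes were small: the median absolute log2 change among the changed genes was 0.24, and 62 genes rose and 94 fell at least 2-fold. The number changed at least 2-fold, 156 here, depended on the handling of low genes, from 17 (FPKM, no filter) to 257 (counts, no filter). In 3579 genes (30.2%) every knockdown library lay beyond every control library, where chance gives 2.86%, and 3054 of these were among the changed genes. The count of changed genes was 5081 (2526 rose, 2555 fell) without BOLA3-L knockdown replicate 1 and between 2841 and 3294 without any other single library.

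Among genes with a mean of at least 5 CPM and no overlap between the groups, the largest fall was that of EHF, an epithelial ETS transcription factor (identifier 26298, chromosome 11, 34621093 to 34663288), which fell from 28.5 ± 0.671 to 5.68 ± 0.946 CPM (SD, n = 4 each; log2 change -2.33, SE 0.0895, adjusted p 2.2e-12). SCD, the stearoyl-CoA desaturase (identifier 6319, chromosome 10, 100347233 to 100364826), fell from 698 ± 5.93 to 240.1 ± 17.8 CPM (-1.54, SE 0.0429, adjusted p 2.0e-14), the smallest p of the comparison. PSMA4, an alpha subunit of the 20S proteasome (identifier 5685, chromosome 15, 78540405 to 78552417), fell from 199 ± 8.02 to 81.0 ± 4.02 CPM (-1.29, SE 0.0443, adjusted p 4.2e-13). The cholesterol exporter ABCA1 fell by 1.64 on the log2 scale, the keratin KRT6A by 1.55, the growth factor BMP7 by 1.49, the interferon-induced IFI44 by 1.44 and the carbonic anhydrase CA9 by 1.32. On log2 FPKM with a pseudocount of 1, which shrinks genes at low levels, the values were -1.46 for EHF, -0.65 for ABCA1 and -0.85 for BMP7.

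Under the same limits on level and overlap, the largest rise was that of WWC3, a regulator of Hippo signalling (identifier 55841, chromosome X, 10015254 to 10144474), which rose from 6.23 ± 0.783 to 20.2 ± 0.663 CPM (SD, n = 4 each; log2 change 1.698, SE 0.0871, adjusted p 8.8e-11). FN1, which encodes fibronectin (chromosome 2, 215360865 to 215436068), rose from 170.2 ± 4.14 to 316 ± 7.48 CPM (0.89, SE 0.0352, adjusted p 2.2e-12). CALB2, the calcium-binding calretinin, rose from 98.0 ± 3.43 to 199 ± 10.1 CPM (1.02). The scavenger receptor OLR1 rose by a log2 change of 1.53, NIPAL2 by 1.33, the alkaline phosphatase ALPP, with 18.1% of its sequence shared with other genes, by 1.26, ZNF704 by 1.23, IGFL1 by 1.18, H6PD by 1.12, the nucleotidase NT5M by 1.11 and the matrix protein MATN2 by 1.01. On log2 FPKM with a pseudocount of 1 the values were 1.06 for WWC3, 1.02 for OLR1, 0.83 for NIPAL2 and 0.43 for ZNF704. By the rule that chose them, all 4 knockdown libraries lay beyond all 4 controls in each of these genes and of the falls named above.

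**Figure D2:**
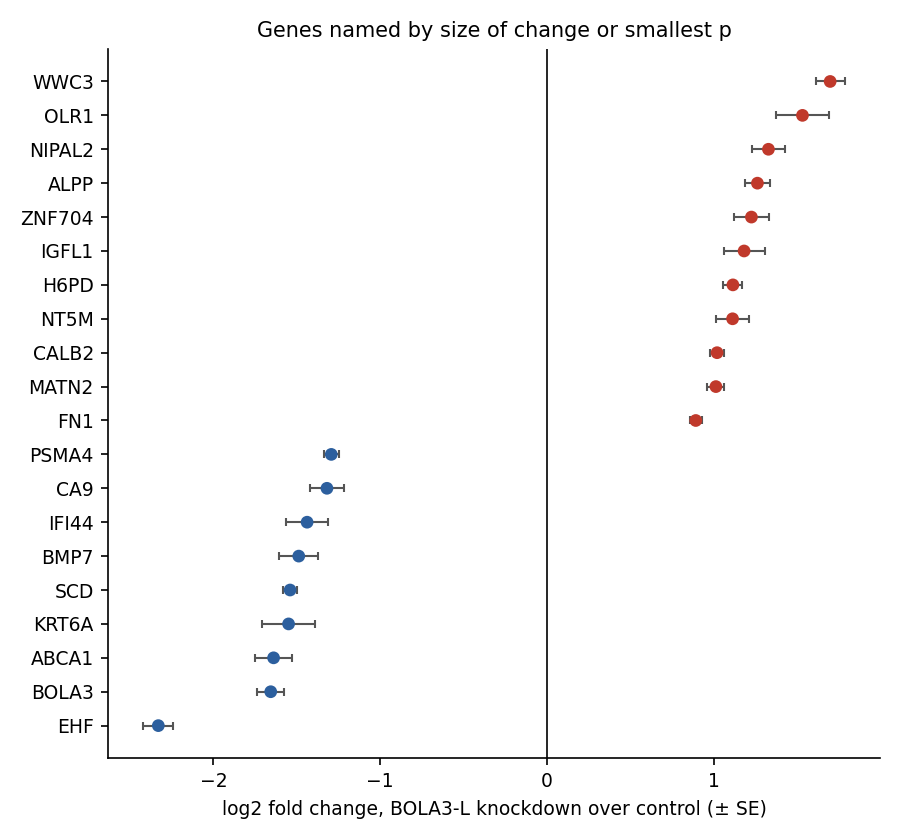
Log2 change (x axis, knockdown over control, with SE bars, 4 libraries per group) of 20 of the genes with the largest changes or smallest p-values; red points rose and blue points fell. Of the genes shown, which have a mean of at least 5 CPM and no overlap between the groups, EHF (-2.33) has the largest fall and WWC3 (1.698) the largest rise.

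Squamous lineage genes fell as a group: 14 of the 15 tested members fell, and 14 did when adjusted over the list alone (median log2 change -0.41, camera adjusted p 3.7e-10, adjusted p = 0.0802 with an estimated correlation). None rose in edgeR (0 at an unadjusted p under 0.05 and 0 in DESeq2). KRT14 fell by 1.14 on the log2 scale, KRT5 by 0.69, the laminin chain LAMB3 by 0.62 and TP63, the transcription factor of the basal squamous lineage, by 0.49. Sequence shared with other genes covers 12.5% of KRT14 and 24.4% of KRT6A, so part of their counts cannot be assigned to 1 gene with certainty. Differentiation genes of the cornified envelope were mostly too low to test: of 12 tested members 4 fell (5 adjusted over the list alone), namely SCEL, KLF4, S100A9 and KLK5, and 0 rose in edgeR (0 at an unadjusted p under 0.05 and 0 in DESeq2). The list did not pass the camera test (adjusted p 0.128). Among junction genes 12 of 27 fell (12 adjusted over the list alone), including the tight junction scaffold TJP1 (-0.29) and the desmosome genes PKP1 (-0.30) and DSG3 (-0.31), while 4 rose (5 adjusted over the list alone), TJP3 by 0.71 together with EPCAM, RAB25 and PPL. That list did not pass either (adjusted p 0.232). Without BOLA3-L knockdown replicate 1, 9 junction genes rose and 13 fell, and 7 fell without control replicate 3 and 8 without control replicate 2 or BOLA3-L knockdown replicate 2.

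Mesenchymal genes moved both ways. Of 22 tested members 9 fell (9 adjusted over the list alone), among them the matrix protein TNC (-0.64) and the transcription factor SNAI2 (-0.52), and 3 rose (3 adjusted over the list alone), which were FN1, CCN1 (0.29) and CCN2 (0.24). The list did not pass the camera test (adjusted p 0.229). VIM (-1.43), ZEB1 (-1.83) and SPARC (-1.42) fell from a low level, with control means of 4.36, 0.799 and 2.79 CPM. Of 16 metalloproteinase and inhibitor genes 7 fell (7 adjusted over the list alone), including MMP2 (-0.88) and MMP14 (-0.40), and 3 rose (4 adjusted over the list alone), the inhibitors TIMP2 (0.44) and TIMP1 (0.21) and the protease MMP15 (0.49), with a camera adjusted p of 0.352. Of 19 YAP/TAZ targets 8 rose (9 adjusted over the list alone), such as CCN1, the kinase NUAK2 (0.49) and WWC1 (0.28), and 3 fell (4 adjusted over the list alone), RBMS3, TGFB2 and FJX1 (camera adjusted p 0.143). Without BOLA3-L knockdown replicate 1, 5 mesenchymal genes rose and 5 YAP/TAZ targets fell. Members beyond the 4 with the smallest p of each list, such as VIM and TIMP1, are named here and in what follows after their values were seen.

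Cholesterol genes fell as a group: of 22 tested members 13 fell and 3 rose (15 and 4 adjusted over the list alone), with a median log2 change of -0.18 (camera adjusted p 0.00081, adjusted p = 0.0802 with an estimated correlation). INSIG1 fell by 0.64 on the log2 scale, and the synthesis enzymes HMGCS1 and FDFT1 by 0.39 and 0.24. PMVK (0.49) and TM7SF2 (0.20) were among the 3 that rose. Fatty acid genes divided: 9 of 23 rose and 7 fell (10 and 8 adjusted over the list alone), with a median of 0.05, a mean of -0.06 and no camera call (adjusted p 0.883, direction up). The synthesis genes SCD, FASN (-0.41) and their activator SREBF1 (-0.80) were among those that fell, as was the acyl-CoA ligase ACSL3 (-0.43), and the oxidation genes HADH (0.91), CPT1A (0.23), CPT2 (0.26) and ACADM (0.20) were among those that rose. The list did not divide cleanly by function, since the oxidation gene ACADVL (-0.24) and PPARA (-0.54) also fell.

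Glycolysis and hypoxia response genes also fell, 17 of 32 tested members against 3 that rose (18 and 4 adjusted over the list alone), with a median log2 change of -0.16 (camera adjusted p 0.00041, adjusted p = 0.237 with an estimated correlation). CA9 fell by 1.32 on the log2 scale, NDRG1 by 0.91 and the pyruvate kinase PKM by 0.37, from 2181 to 1692 CPM. The glucose transporter SLC2A3 (0.42, with 13.0% of its sequence shared), ADM (0.21) and PFKFB3 (0.14) rose, and 5 members rose without BOLA3-L knockdown replicate 1.

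NRF2 genes rose: 11 of 24 tested members rose and 1, the glutathione reductase GSR (-0.16), fell (11 and 1 adjusted over the list alone). The median log2 change was 0.14 (camera adjusted p 0.00085, adjusted p = 0.201 with an estimated correlation). TXNRD1 rose by 0.44, the transporter ABCC3 by 0.47, NQO1 by 0.35 and the amino acid transporter chain SLC3A2 by 0.28. Without BOLA3-L knockdown replicate 1, 12 rose and 2 fell. Of 16 genes of iron uptake, storage and export, 3 rose and 3 fell (3 and 3 adjusted over the list alone). The ferritin chains FTH1 (0.23, with 34.0% of its sequence shared) and FTL (0.12) and the transferrin receptor TFRC (0.17) rose, and HMOX2 (-0.33), PCBP1 (-0.15) and NCOA4 (-0.13) fell. The iron list was not called (adjusted p 0.963; its median is -0.02 and its mean 0.03), and 5 of its genes rose without BOLA3-L knockdown replicate 1 and 2 without control replicate 3 or 4 or BOLA3-L knockdown replicate 2 or 4.

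In the pathway of BOLA3 itself few genes changed. Of 21 tested genes for mitochondrial iron-sulfur cluster assembly, ISCA2 fell (log2 change -0.48, adjusted p 4.9e-05) and GLRX5 rose (0.11, adjusted p 0.0333), while adjusted over the list alone 0 rose and 1 fell; the camera adjusted p was 0.671. GLRX5 kept its call without BOLA3-L knockdown replicate 1, where 4 genes of the list rose, and lost it without any other single library (adjusted p from 0.0510 to 0.0915). Of 10 cytosolic assembly genes CIAO2A (0.26) and CIAO2B (0.11) rose and MMS19 (-0.17) fell (2 and 1 adjusted over the list alone; camera adjusted p 0.690). CIAO2B lost its call without BOLA3-L knockdown replicate 2 or 4 or any single control library (adjusted p from 0.0525 to 0.139). Its log2 change was 0.07 with GC-corrected offsets and without BOLA3-L knockdown replicate 1. In the list 5 genes rose without that library, and 2 fell without BOLA3-L knockdown replicate 2. Of 19 genes of lipoic acid synthesis and lipoylated enzymes DBT (0.19), BCKDHB (0.20) and MCAT (0.22) rose and PDHX (-0.14) fell (2 and 0 adjusted over the list alone; camera adjusted p 0.379). Those calls were lost without control replicate 1 or 3 for DBT (adjusted p 0.0798 and 0.0670), without control replicate 1 or 2 or BOLA3-L knockdown replicate 2 for BCKDHB (0.0508 to 0.0609), without any single library other than control replicate 3 and BOLA3-L knockdown replicate 1 for MCAT (0.0561 to 0.149), and without any other than control replicate 1 and BOLA3-L knockdown replicate 1 for PDHX (0.0631 to 0.136). The number of these genes that rose therefore ranged from 0 without control replicate 1 to 3 without BOLA3-L knockdown replicate 1.

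Neither list of respiratory chain genes passed the camera test, and their counts moved when single libraries were left out. Of 37 complex I subunits 8 rose, such as NDUFS1 (0.21) and NDUFAB1 (0.24), and NDUFA12 (-0.24) fell (8 and 1 adjusted over the list alone; camera adjusted p 0.138). Of 39 nuclear-encoded subunits of complexes II to V, 8 rose, such as COX5B (0.22) and SDHA (0.21, with 11.8% of its sequence shared), and UQCRC2 (-0.17) fell (7 and 1 adjusted over the list alone; camera adjusted p 0.0981). Without BOLA3-L knockdown replicate 1, 15 complex I subunits rose and 2 fell, 16 subunits of complexes II to V rose and 2 fell, and both lists passed the camera test (adjusted p 0.0373 each; 0.0373 to 0.645 for complex I and 0.0220 to 0.638 for complexes II to V over all alternatives run). The list of complexes II to V also passed without BOLA3-L knockdown replicate 3 (adjusted p 0.0333), with no filter on low counts (adjusted p 0.0451) and with GC-corrected offsets and without BOLA3-L knockdown replicate 1 (adjusted p 0.0220). In complex I, 4 subunits rose without control replicate 2 or BOLA3-L knockdown replicate 2 and 5 without control replicate 3 or BOLA3-L knockdown replicate 3. Of 17 citric acid cycle genes 5 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p 0.485). IDH2 (0.46), FH (0.26), SUCLG2 (0.28) and MDH2 (0.18) were among those that rose. ACO1 (-0.37), ACLY (-0.15) and IDH3B (-0.19) fell, and 8 genes rose without BOLA3-L knockdown replicate 1. Of 51 mitochondrial ribosomal protein genes 9 fell, MRPS7 (-0.32) and MRPL40 (-0.29) among them, and 5 rose, which were MRPL16, MRPL24, MRPS16, MRPS35 and MRPL38 (9 and 5 adjusted over the list alone; camera adjusted p 0.671). The rises in that list numbered 9 without BOLA3-L knockdown replicate 1, 0 without BOLA3-L knockdown replicate 2, 1 without control replicate 2, 3 or 4, 2 without BOLA3-L knockdown replicate 3 and 3 without BOLA3-L knockdown replicate 4, and the falls 5 without control replicate 1 or BOLA3-L knockdown replicate 3. The table lists 0 of the 13 mitochondrially encoded mRNAs, so these were not assessed.

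Mitotic genes fell slightly: 17 of 46 tested members fell (19 adjusted over the list alone), with a median log2 change of -0.07 (camera adjusted p 0.0035, adjusted p = 0.528 with an estimated correlation). In edgeR 0 rose (0 at an unadjusted p under 0.05 and 0 in DESeq2). The proliferation marker MKI67 fell by 0.24 on the log2 scale, and the kinases AURKA and PLK1 by 0.21 and 0.20. The median of the list against the control mean was -0.02 in BOLA3-L knockdown replicate 1 and -0.10 to -0.07 in the other knockdown libraries. Without BOLA3-L knockdown replicate 1, 29 members fell. The members have a median transcript GC content of 42.6%, against 48.8% over tested genes. In the fit without that library log2 changes ran with GC content (Spearman rho 0.207), so the count of 29 can carry that trend. Cytosolic ribosomal protein genes rose, 16 of 61 (15 adjusted over the list alone), with a median of 0.06 (camera adjusted p 0.0063, adjusted p = 0.645 with an estimated correlation) and 0 falls in edgeR (1 at an unadjusted p under 0.05 and 0 in DESeq2). RPL34 rose by 0.25, RPLP2 by 0.16 and RPS19 by 0.17. The ribosomal median was 0.0076 in BOLA3-L knockdown replicate 1 and 0.05 to 0.11 in the others. Without that library 36 rose and 1 fell. Fewer rose without some others, 7 without control replicate 2 or BOLA3-L knockdown replicate 2 and 9 without control replicate 1 or 3 or BOLA3-L knockdown replicate 3. The camera call was lost without BOLA3-L knockdown replicate 2 (adjusted p 0.0837; 9.8e-05 to 0.645 over all alternatives run). Of 32 genes for heterogeneous ribonucleoproteins and SR splicing factors 11 fell (11 adjusted over the list alone), SRSF6 and SRSF2 by 0.21 and HNRNPL by 0.19, the last with 28.1% of its sequence shared. That list passed the camera test (adjusted p 0.0083, adjusted p = 0.418 with an estimated correlation), and 0 rose in edgeR (1 at an unadjusted p under 0.05 and 0 in DESeq2).

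DNA replication genes went both ways, with 11 of 48 falling and 7 rising (11 and 7 adjusted over the list alone; camera adjusted p 0.247). The ribonucleotide reductase subunit RRM2 (-0.34, with 27.8% of its sequence shared) and the helicase subunits GINS2 (-0.33) and MCM3 (-0.18) fell, and the cyclin CCNE2 (0.47) rose. Of 11 replication-dependent histone genes H2BC12 (46.2% of its sequence shared), H2AC6, H2AC11 and H1-2 rose (4 adjusted over the list alone; camera adjusted p 0.128), and 0 fell in edgeR (0 at an unadjusted p under 0.05 and 0 in DESeq2). H1-2 lost its call without control replicate 2 or BOLA3-L knockdown replicate 2 (adjusted p 0.0581 and 0.0560). Of 25 p53 targets XPC (0.24) and BTG2 (0.34) rose and GADD45A (-0.25) and CCNG1 (-0.18) fell (2 and 2 adjusted over the list alone; camera adjusted p 0.982). Without BOLA3-L knockdown replicate 1, 5 p53 targets rose and 16 replication genes fell. CCNG1 lost its call without control replicate 1, 2 or 4 or BOLA3-L knockdown replicate 3 (adjusted p 0.0579 to 0.0751). Among 28 apoptosis genes 4 fell (4 adjusted over the list alone), APAF1 (-0.69) and BCL2L1 (-0.21) among them, and 0 rose in edgeR (1 at an unadjusted p under 0.05 and 0 in DESeq2). The apoptosis list was not called (adjusted p 0.671; median 0.03, mean -0.06, direction down), and 8 fell and 2 rose without BOLA3-L knockdown replicate 1.

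Stress and signalling lists held changes in both directions. Of 30 ATF4 targets 11 fell, DDIT4 (-0.42) and ATF3 (-0.34) among them, and 7 rose, SLC7A5 (0.29) among them (12 and 10 adjusted over the list alone; camera adjusted p 0.537). Without BOLA3-L knockdown replicate 1, 12 rose and 12 fell, and 7 fell without control replicate 2 or 3. Of 20 genes of the unfolded protein response XBP1 (0.25), EDEM1 (0.24) and DNAJB9 (0.31) rose and HSPA5 (-0.26), DNAJB11 (-0.17, with 16.1% of its sequence shared), PDIA6 (-0.11) and HERPUD1 (-0.15) fell (3 and 4 adjusted over the list alone; camera adjusted p 0.883; median -0.01, mean 0.0036, direction down). Without control replicate 1, which also ended the call of DNAJB11 (adjusted p 0.0679), 1 fell; 2 fell without BOLA3-L knockdown replicate 3 and 7 without BOLA3-L knockdown replicate 1. Of 27 immediate early and ERK target genes 12 fell and 6 rose (13 and 6 adjusted over the list alone; camera adjusted p 0.167), with JUN at -0.48, IER3 at -0.46 and EGR1 at 0.38. Of 20 NF-kB and cytokine genes IL6 (0.93, adjusted p 1.1e-07), PTGS2 (0.76, and 0.41 on log2 FPKM with a pseudocount of 1), NFKB2 and TNFAIP2 rose and IL1B (-0.80, adjusted p 1.0e-10), IL1A (-0.43), CXCL8 (-0.93), NFKBIA and IL11 fell (4 and 6 adjusted over the list alone; camera adjusted p 0.690). The NF-kB rises numbered 2 without any single library other than BOLA3-L knockdown replicate 1. Of 28 interferon response genes IFI44 (-1.44), SAMD9 (-0.37), STAT2, IRF9 and IFIT1 fell and OAS3 (0.22), USP18 (0.44, with 19.3% of its sequence shared) and HERC6 rose (6 and 4 adjusted over the list alone; camera adjusted p 0.690), and 3 fell without control replicate 3 or BOLA3-L knockdown replicate 4. Of 16 antigen presentation genes PSMB9 (0.29, with 10.3% of its sequence shared) and ERAP2 (0.17) rose and TAP2 (-0.17, with 35.6% of its sequence shared) and HLA-E (-0.11) fell (2 and 2 adjusted over the list alone; camera adjusted p 0.963; median 0.03, mean -0.02, direction up). ERAP2 lost its call without control replicate 1, 2 or 3 or BOLA3-L knockdown replicate 2 or 3 (adjusted p 0.0747 to 0.127), and HLA-E without control replicate 3 or 4 (0.0638 and 0.0623). In all, 6 antigen presentation genes rose without BOLA3-L knockdown replicate 1.

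Few markers of other cell types had enough counts to be tested. Control means were 11.7 CPM for COL1A1, 80.9 CPM for CD68 and 0.420 to 0.993 CPM for LUM, CSF1R, CDH5 and ESAM. Of 10 fibroblast markers 2 were tested, and COL1A1 (-1.28) and LUM (-1.53) both fell (on log2 FPKM with a pseudocount of 1 and no minimum, -0.70 and -0.20; 2 adjusted over the list alone; camera adjusted p 0.128), with 0 rises in edgeR (0 at an unadjusted p under 0.05 and 0 in DESeq2). LUM lost its call without control replicate 2 or 3 or BOLA3-L knockdown replicate 2 (adjusted p 0.0579 to 0.0657). Of 12 leukocyte markers CD68 (-0.09, adjusted p 0.123) and CSF1R (-0.12, adjusted p 0.797) were tested and 0 changed in edgeR (1 at an unadjusted p under 0.05, 0 in DESeq2, 0 adjusted over the list alone; camera adjusted p 0.671). CD68 shares 90.4% of its sequence with other transcripts and passed without BOLA3-L knockdown replicate 1, both as counted (adjusted p 0.0129) and with GC-corrected offsets (adjusted p 0.0016), and in no other alternative run (up to 0.321). Of 9 endothelial markers CDH5 (0.79, and 0.20 on log2 FPKM with a pseudocount of 1 and no minimum) rose (1 adjusted over the list alone) and ESAM (0.08, adjusted p 0.884) did not pass, with 0 falls in edgeR (0 at an unadjusted p under 0.05 and 0 in DESeq2; camera adjusted p 0.485).

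**Figure D3:**
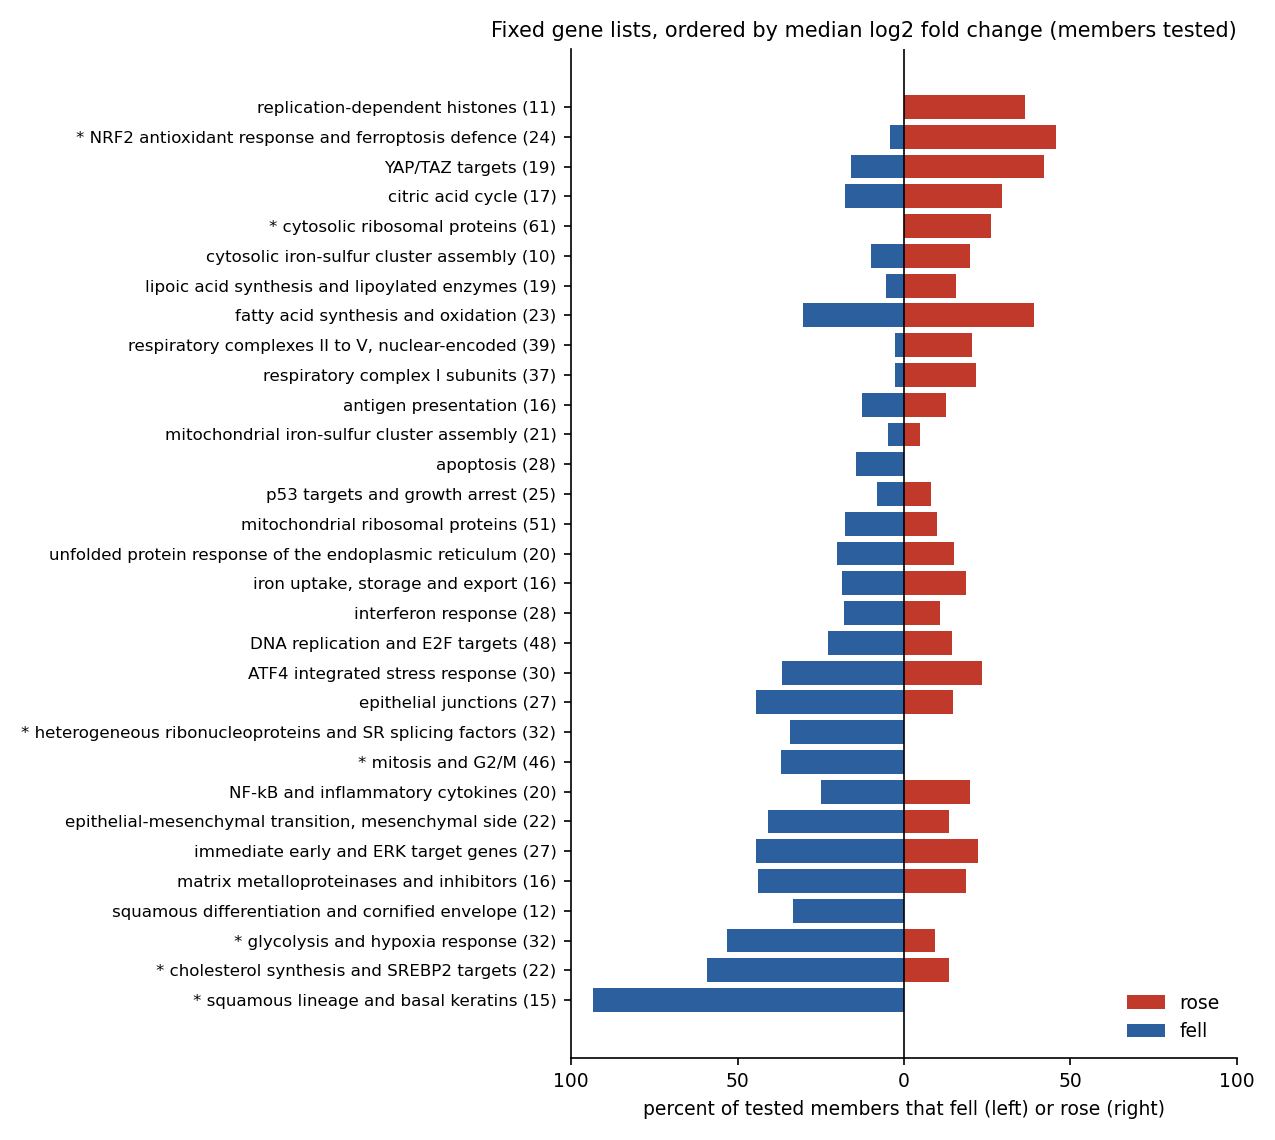
Percent of tested members (x axis) that fell (blue, left) or rose (red, right) after BOLA3-L knockdown in each gene list with at least 10 tested members, ordered by median log2 change, with the number tested in brackets; a star marks the 7 lists with a camera adjusted p under 0.05. With the correlation estimated from the libraries 0 lists passed. Squamous lineage genes have the largest share that fell.

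Epidermal, adhesion and hypoxia terms were over-represented among the genes that fell. Among these, 117 of 2932 gene ontology terms and 11 of 307 KEGG pathways were over-represented by Fisher's exact test, against 15.6% of all tested genes that fell. Epidermis development came first, with 24 of 37 members falling and 5 rising (adjusted p 5.3e-08). In hemidesmosome assembly, the anchoring of basal cells to the matrix, 10 of 12 members fell (adjusted p 0.00012), among them COL17A1 (-0.41), ITGA6 (-0.40) and DST (-0.43). In cell adhesion 62 of 197 fell and 28 rose (adjusted p 1.3e-05), and in the response to hypoxia 38 of 106 fell and 13 rose (adjusted p 9.5e-05). In positive regulation of epithelial to mesenchymal transition 16 of 32 fell and 1 rose (adjusted p 0.00083), and in the PI3K-Akt pathway 59 of 212 fell and 32 rose (adjusted p 0.00058). The hypoxia-inducible factor subunit HIF1A fell from 306 ± 7.98 to 198 ± 11.6 CPM (SD, n = 4 each; log2 change -0.63) and the caveolin CAV1 by 0.64 on the log2 scale. Among genes that rose, 3 gene ontology terms and 9 KEGG pathways were over-represented, against 15.0% of all tested genes that rose. Camera over the same terms, at the preset correlation of 0.01, called 5 in place of 140. Hemidesmosome assembly (adjusted p 2.4e-05), epidermis development (adjusted p 0.0069) and positive regulation of epithelial to mesenchymal transition (adjusted p 0.0426) were lower. The degradation of valine, leucine and isoleucine (adjusted p 0.0205) and fatty acid elongation (adjusted p 0.0230) were higher. Camera on terms was not run with an estimated correlation or on other splits of the libraries. The term members in this paragraph were chosen after their values were seen.

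None of the 7 list calls held with the correlation estimated from the libraries, where 0 lists passed and 4 had an unadjusted p under 0.05, and other splits of the libraries gave up to 6 calls with the preset correlation. The number of hairpins and their sequences are not given in the sources used here, so effects of the hairpin itself cannot be set apart from effects of BOLA3 loss.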

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

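Among the tests below, that of admixed cells was chosen only after the result was seen, as were the GC-corrected offsets and the removal of genes with near-identical copies.

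BOLA3-L knockdown replicate 1 stood apart from the other knockdown libraries. Across genes, which are not independent replicates, its deviation from the other knockdown libraries ran with transcript GC content (Spearman rho -0.6987, against 0.238 to 0.532 in the other knockdown libraries and -0.096 to 0.128 in the controls). The other knockdown libraries were set against means that include replicate 1. Against the control mean rho was -0.3919 in replicate 1 and 0.1253 to 0.2591 in the others. Without replicate 1 the log2 changes ran with GC content (rho 0.207, main fit 0.0364), so counts without it can carry that trend. A correction for GC content lowered the SD of replicate 1's deviation from the other knockdown libraries from 0.2503 to 0.2017, where those libraries lie between 0.179 and 0.192. GC-dependent recovery in replicate 1 may thus account for part of its deviation. Weaker knockdown or admixed control cells are argued against: the library lay no nearer the controls on the first principal component (shift of -0.0135 of the distance between the groups) and had the lowest BOLA3 of the 4 (6.06 CPM). No biological explanation was tested.

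The 100 genes whose replicates scatter most for their level were often genes with copies. Of the 95 with a value 34 (35.8%) had a near-identical copy, against 3.51% of the other tested genes, a ratio of 10.2 (Fisher's exact p 9.2e-25), which is consistent with reads that cannot be placed. The library that stands apart may add another part, since 38 of the 100 remained among the most scattered without BOLA3-L knockdown replicate 1 and 77 to 84 did without any other single library. Of the 100 genes, 9 changed between the groups. No biological explanation was tested.

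Single libraries stood apart from the other 3 of their group by Dixon's gap ratio in 24 of 300 groups of values, where chance gives about 1 in 20, or 15. The ratio sets the gap to the nearest library against the range of the group. A flagged value can thus lie close to the others, as for KIF20A and PLK1 below. The groups were of named genes, library totals and positions on the first principal components, and all 24 were of named genes. Of the 24, 15 were in BOLA3-L knockdown replicate 1. With the GC correction, checked for named genes only, the count was 17 of 294, near 1 in 20, and 7 of the 17 were in that library. Values are in CPM with the lowest and highest of the other 3 libraries in brackets. In BOLA3-L knockdown replicate 1, NIPAL2 stood at 14.52 (11.58 to 12.02), IGFL1 at 6.245 (7.67 to 7.86), SCD at 266.7 (229 to 233) and CA9 at 4.629 (5.13 to 5.20). In the same library FH stood at 86.26 (81.9 to 82.3), PKM at 1532.4 (1720 to 1758), HMOX2 at 62.14 (69.4 to 70.2) and TFRC at 350.7 (304 to 310.0). TXNRD1 there was at 347.9 (320.0 to 324), PLK1 at 206.7 (210.2 to 210.9), TJP1 at 403.7 (361 to 368) and TJP3 at 8.591 (12.4 to 12.7). MMP14 there was at 236.4 (271 to 275), IL1A at 52.72 (43.8 to 45.2) and H2AC6 at 7.418 (9.16 to 9.44). In BOLA3-L knockdown replicate 4, RPS19 stood at 419.1 (434 to 436). In control replicate 1, HNRNPC stood at 843.0 (783 to 791), IFI44 at 11.21 (9.50 to 9.79) and KIF20A at 187.9 (185.7 to 186.0). In control replicate 2, FDX1 stood at 30.19 (32.5 to 32.8) and MKI67 at 1091.5 (999.7 to 1013). In control replicate 3, CCNG1 stood at 96.50 (104 to 106), and in control replicate 4, FH stood at 73.27 (68.1 to 68.2) and PCBP1 at 290.1 (305 to 307).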

How the results depend on the processing

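Tests chosen only after the result was seen were the GC-corrected offsets, with and without BOLA3-L knockdown replicate 1, and the removal of genes with near-identical copies.

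The log2 change of BOLA3 lay between -1.71 and -1.56 in every alternative run. Of the 138 other named genes called, 126 kept direction and call in up to 20 alternatives, 12 lost the call in at least 1 and 0 reversed. These genes were chosen for large changes or small p-values, so this does not show how stable other calls are. Of all 3630 calls, 2794 were shared without control replicate 2 and 2794 with FPKM and no filter, the fewest. The most, 3620, were shared with RLE size factors. All shared calls kept their direction. Changed genes numbered 3055 to 3741 across normalizations, filters, DESeq2 and FPKM, 2841 to 5081 with 1 library left out, 4907 with GC-corrected offsets and 4984 with these and without BOLA3-L knockdown replicate 1. DESeq2 shared 3602 calls with the same direction. Genes changed at least 2-fold, 156 by edgeR, numbered 257 with no filter, 91 with at least 1 CPM in 4 libraries, 18 and 54 with FPKM pseudocounts of 1 and 0.1, and 17 with FPKM and no filter. The added pseudocount shrinks low genes by construction (WWC3 1.06, EHF -1.46), and the filters change which low genes are tested. With 1 library left out they numbered 155 to 182. The 7 lists called became 0 with an estimated correlation and 16 with fry, which tests each list on its own, and were 6 to 9 with 1 library left out. Terms numbered 140, 5 with camera at the preset correlation, which compares whole lists rather than calls, and 129 to 167 with 1 library left out. Ribosomal protein genes were not called by fry (adjusted p 0.0930; 9.8e-05 to 0.645 over all alternatives of that list), nor splicing factors with GC-corrected offsets and without BOLA3-L knockdown replicate 1 (adjusted p 0.0888; 0.0020 to 0.418 over all alternatives of that list). The fatty acid list reversed to lower with fry (adjusted p 0.00711; up to 0.998 in the others). Directions also turned for genes that had not passed: with 1 library left out the log2 change ranged from -0.013 (without BOLA3-L knockdown replicate 1) to 0.073 for E2F7, from -0.321 to 0.021 for CSF1R and from -0.118 to 0.279 for ESAM, and ESAM was at -0.086 with GC-corrected offsets and without BOLA3-L knockdown replicate 1; the cause was not tested. With the replicate number as a block 3392 genes changed (3322 shared), 158 at least 2-fold, with 7 lists, 142 terms and BOLA3 at -1.66. For 1 of 4 replicate numbers the control and knockdown libraries were each other's best match. Correlations between libraries of the same number were -0.0444 to 0.0876. Pairing by number was thus not found, but so few libraries cannot rule it out. Depth limits genes with few counts: 3 counts are 0.0854 to 0.0962 CPM.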

Other observations

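Among the tests below, none on the splits or the hairpin was chosen only after the result was seen; the term members named were chosen after their values were seen.

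Terms for branched-chain amino acid degradation, fatty acid beta-oxidation and lysosomes were over-represented among the genes that rose after BOLA3-L knockdown. Of those in this paragraph, camera at the preset correlation called the degradation of valine, leucine and isoleucine alone (adjusted p 0.0205). An estimated correlation was not run on terms. In the degradation of valine, leucine and isoleucine 20 of 40 members rose and 2 fell (Fisher's exact adjusted p 6.2e-05), among them HADH (log2 change 0.91), OXCT1 (0.41), ACAA2 (1.24, from a low level of 1.67 CPM) and PCCB (0.21). In fatty acid beta-oxidation 17 of 37 rose and 4 fell (adjusted p 0.0106), with ACADVL (-0.24) among the falls. In the lysosome pathway 36 of 112 rose and 9 fell (adjusted p 0.00041), among them the acetyltransferase HGSNAT (0.98), the sorting receptor SORT1 (0.39), the acid lipase LIPA (0.32) and the saposin precursor PSAP (0.22), while IGF2R (-0.22) fell. In glycosaminoglycan degradation 9 of 16 rose and 1 fell (adjusted p 0.0122).

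Genes of circadian regulation fell more often than others: 23 of 51 fell and 6 rose (adjusted p 0.00016), with the clock repressor BHLHE40 going from 69.2 to 39.1 CPM (-0.82), PER1 (-0.42), NRIP1 (-0.44) and PPARA (-0.54) among the falls and HDAC1 (0.25) among the rises. In histone H3-K4 trimethylation 9 of 14 fell (adjusted p 0.0040), including SETD1A (-0.22), SETD1B (-0.22) and KMT2A (-0.18). In Notch signalling 24 of 69 fell and 11 rose (adjusted p 0.0051), and in tRNA aminoacylation 13 of 35 fell and 4 rose (adjusted p 0.0437). Camera called no term of this paragraph.

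PSMA4 fell by 1.29 on the log2 scale, while of 42 other tested proteasome genes, the immunoproteasome subunits not counted, 1 rose (PSME1, 0.25) and 2 fell (PSMF1, -0.18, and PSME4, -0.18), with a median of -0.01; the immunoproteasome subunit PSMB9 also rose (0.29). A candidate explanation for PSMA4, EHF and SCD is binding of the hairpin to other transcripts, tested on the sequence of exon 3 since the hairpin's own is not given. The search covered the exon and 6 bases on each side. A long match to that stretch is argued against, since the longest run that any of the 3 shares with it is 10 bases, the median over 11788 genes. A hairpin that reaches beyond that stretch was not covered, so a long match to such a hairpin stays open. A 7-base seed match stays open: the lowest mean residual over 95 seeds was -0.0595, as low as in a share of 0.053 of 1000 random sets, and simulated shifts of -0.1 were found in 14 of 20 runs. None of the 3 genes carries that lowest seed in the 3′ untranslated region of the transcript used. The other seeds were not looked up in these genes, so this does not argue against a seed match in them. A direct effect of BOLA3 loss on them was not tested.

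Other splits of the 8 libraries into 4 and 4 were compared with the real one. In 1 of 35 splits, the real one, the count of changed genes was as large (3630, highest other 0 in edgeR). Every other split puts libraries of both groups on each side. The difference between the groups then widens the spread within a side and lowers the count. The other splits therefore do not show what chance alone gives, and they cannot exclude chance for that count. The counts of genes changed at least 2-fold (156, highest other 0) and of terms (140, highest other 0) are drawn from the changed genes and had to be 0 in the other splits, so they add no separate evidence. For lists the real split also gave the most (7), but other splits with 0 changed genes in edgeR gave up to 6, and the real groups gave 6 without BOLA3-L knockdown replicate 2, so chance is not excluded for the list calls. At an unadjusted p under 0.05 the real split gave 4831 genes and the highest other 1747, with a median of 194 over the other splits and 592 expected by chance; DESeq2 was not run on the splits.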
